A study of Mus musculus with 14 samples.

How the data were processed

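RNA was sequenced from the lateral central amygdala of mice, as RNA immunoprecipitated from SOM+ neurons (10 libraries) and as input RNA of the tissue (4 libraries). A pool of 8 to 12 mice stood behind each library. The deposited normalised counts hold a signal per gene and library: read counts divided by the authors by 1 size factor per library. Every nonzero value was a whole multiple of 1 step per library (100% of values within 0.01 reads), so whole reads were recovered by dividing by that step. The authors' comparison table gives a log2 fold change with its standard error, a Wald score and a p-value with its adjusted form per gene, per the file headers, together with a mean signal. STAR, featureCounts and DESeq2 and the build mm10 are named per the submitters' processing notes. No reads were aligned here.

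The recovered depth was 7787009 to 18523051 reads in IP and 4433890 to 6321466 reads in input. Where a library had no reads of a gene, the level of 3 reads is given as the limit. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The ribosomal RNA gene Rn45s took up to 19.3% of the reads of a library and was left in the totals.

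Of 24048 genes, 5319 had no reads in any library, and 13305 with a mean normalised count of at least 10 over the 14 libraries were tested. Groups were taken from the labels. Values were compared as log2(normalised count + 1) with limma 3.58.1 (mean-variance trend, robust empirical Bayes) in R 4.3.3. Benjamini-Hochberg adjustment covered all tested genes, with a threshold of 0.05. IP was compared with input over all 14 libraries without covariates. Sex in IP, sex in input, IP against input within each labelled sex and the interaction were contrasts in a model of 4 group means. Sst was also tested with a two-sided exact permutation test. Values after ± are standard deviations of normalised counts, and SE is the standard error of a limma log2 fold change.

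Gene lists for cell types, peptides, receptors, channels and RNA classes were written before the data were examined. The 26 lists with at least 5 tested members were compared with other genes by camera with a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and the rotation test fry as alternatives. The blood list (1 member tested) and the mitochondrially encoded genes (0 of 15 in the table) were not tested.

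The named genes follow a rule fixed before the data were examined. It covers Sst and sex-linked genes, and the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 100. It adds up to 4 called members each way per list (where fewer than 2 passed, up to 3 of the most abundant), up to 5 genes each way per sex contrast, and up to 5 each way by adjusted p. Pdyn, Crh, Tac2, Nts, Prkcd, Penk, Npy, Cartpt, Gad1, Gad2, Slc17a7, Gfap and Mbp could be named whatever their values. The rule gave 129 genes, of which 87 are used.

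Alternatives were pseudocounts of 0.5 and 8, no filter and a filter of 50, TMM, upper-quartile and quantile scaling, sample quality weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, each library left out in turn, a replicate block, the 8 libraries with a shared sex and number, sex as a covariate, and the IP or input libraries alone. Chosen after seeing the data were the fit without IP_Female replicates 1 and 4, removal of the trend on gene span within libraries (first with library means kept, then with library medians kept), exchanged sex labels of the input libraries, and 10000 random lists matched on expression. Positions and spans, the distance between the outer ends of a gene, come from the RefSeq annotation of GRCm38.p6, which matched 13251 of the tested genes (99.6%). Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

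The procedure was tested on simulated data with the spread of these libraries and 200 changed genes among 13305. With limma, 1% of the 2-fold and 22% of the 4-fold changes were recovered with 0 false calls, and the median log2 fold change of unchanged genes was -0.54. For 4-fold changes edgeR recovered 29% and DESeq2 45%. Sample quality weights gave 840 false lower calls. Of 4-fold changes confined to female IP, 30% were recovered between the sexes in IP, 9% within females and 0% in the interaction. Between the sexes in IP there were also 2 false higher and 7 false lower calls.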

Results

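RNA was sequenced from the lateral central amygdala (CeL) of mice, a forebrain nucleus made up mostly of inhibitory neurons, in 14 libraries of 4 groups. The 10 immunoprecipitated libraries (IP) hold RNA pulled down from somatostatin-positive (SOM+) neurons, and the 4 input libraries hold RNA of the whole tissue. There were 6 IP libraries labelled male (IP_Male), 4 labelled female (IP_Female), 2 input libraries labelled male (Input_Male) and 2 labelled female (Input_Female), and each library came from a pool of 8 to 12 mice. The recovered depth was 7787009 to 18523051 reads in IP and 4433890 to 6321466 reads in input. IP libraries varied far more between replicates: the median standard deviation of a gene on the log2 scale was 1.07 in IP_Male and 1.18 in IP_Female, against 0.127 and 0.140 in the input groups. Reads were found for 11697 to 14472 genes per IP library and for 15507 to 16387 genes per input library. The ribosomal RNA gene Rn45s took 2.62% to 19.3% of the reads of a library, with the highest share in IP_Male replicate 4. The design asks which transcripts are enriched in SOM+ neurons relative to the surrounding tissue. IP RNA was pulled down with ribosomes and input RNA was not. No library holds RNA pulled down from other cells, so enrichment in SOM+ neurons and effects of the pulldown itself cannot be told apart.

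Sst, which encodes the somatostatin that defines the targeted neurons, was far higher in IP than in input. Its normalised count was 44550 ± 13240 (SD, n = 10) in IP and 7665 ± 1473 (SD, n = 4) in input, and all 10 IP libraries lay above the highest input library. The log2 fold change was 2.51 (SE 0.18, limma adjusted p = 1.04e-09). A two-sided exact permutation test over all 1001 splits gave p = 0.000999, the smallest value it can give. Sst lies on chromosome 16 from 23889573 to 23891342 (GRCm38.p6). By label the level was 39190 ± 8940 (SD, n = 6) in IP_Male and 52590 ± 15790 (SD, n = 4) in IP_Female.

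Several other peptide transcripts of the central amygdala moved with Sst, and others moved against it. Pdyn, the precursor of dynorphin, rose from 2047 ± 251.3 (SD, n = 4) normalised counts in input to 6565 ± 1629 (SD, n = 10) in IP, a log2 fold change of 1.65 (SE 0.20, limma adjusted p = 1.65e-06). Tac2, the neurokinin B precursor, and Npy, neuropeptide Y, rose by 1.20 and 1.65 on the log2 scale. Penk, the enkephalin precursor, was abundant in both fractions but fell from 21950 ± 2017 (SD, n = 4) to 9410 ± 2604 (SD, n = 10), a log2 fold change of -1.27 (SE 0.19, limma adjusted p = 3.95e-05). Cck and Cartpt fell by 1.54 and 3.71 on the log2 scale. Each of these genes lay on one side of all 4 input libraries in every IP library. In the list of central amygdala neuropeptides, 4 of 14 measured members were higher, 3 were lower and 7 did not pass, and 5 higher and 3 lower passed when adjusted over the list alone. That list did not stand apart from other genes (camera adjusted p = 0.109), except on the higher side without Input_Female replicate 2 (0.0475) and in settings with no filter or the span trend removed (0.0370, and 0.000533 and 0.00134). Pdyn lies on chromosome 2 from 129686549 to 129699938 and Penk on chromosome 4 from 4133536 to 4138815 (GRCm38.p6).

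Several other markers of CeL neurons did not pass with limma. Nts had a log2 fold change of 1.10 (limma adjusted p = 0.0632, 0.0416 with edgeR and 0.00706 with DESeq2). Crh stood at 136.8 ± 47.0 (SD, n = 10) normalised counts in IP and 57.7 ± 13.8 (SD, n = 4) in input. Its log2 fold change was 1.15 (limma adjusted p = 0.302, 0.291 with edgeR and 0.0728 with DESeq2). The authors' deposited table called both higher, Nts at 1.19 (adjusted p = 0.0218) and Crh at 1.16 (0.0223). Both also passed with limma with the span trend removed and library means kept (adjusted p = 0.0462 and 0.0202). Prkcd, which marks the other large class of CeL neurons, stood at 929.5 ± 481.8 (SD, n = 10) in IP and 686.2 ± 105.1 (SD, n = 4) in input (log2 fold change 0.29, limma adjusted p = 0.678). The GABA-synthesis genes Gad1 and Gad2 had log2 fold changes of 0.56 and 0.07 and did not pass, nor did the transcription factor Meis2 (0.25, limma adjusted p = 0.453). Among 22 markers of the CeL, 2 were higher (Sst and Tac2) and 4 were lower, and 3 and 4 passed when adjusted over the list alone (camera adjusted p = 0.575). The lower members included the neurotrophin receptor Ntrk2 (log2 fold change -0.88) and the calcium buffer Calb1 (-1.19).

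**Figure D1:**
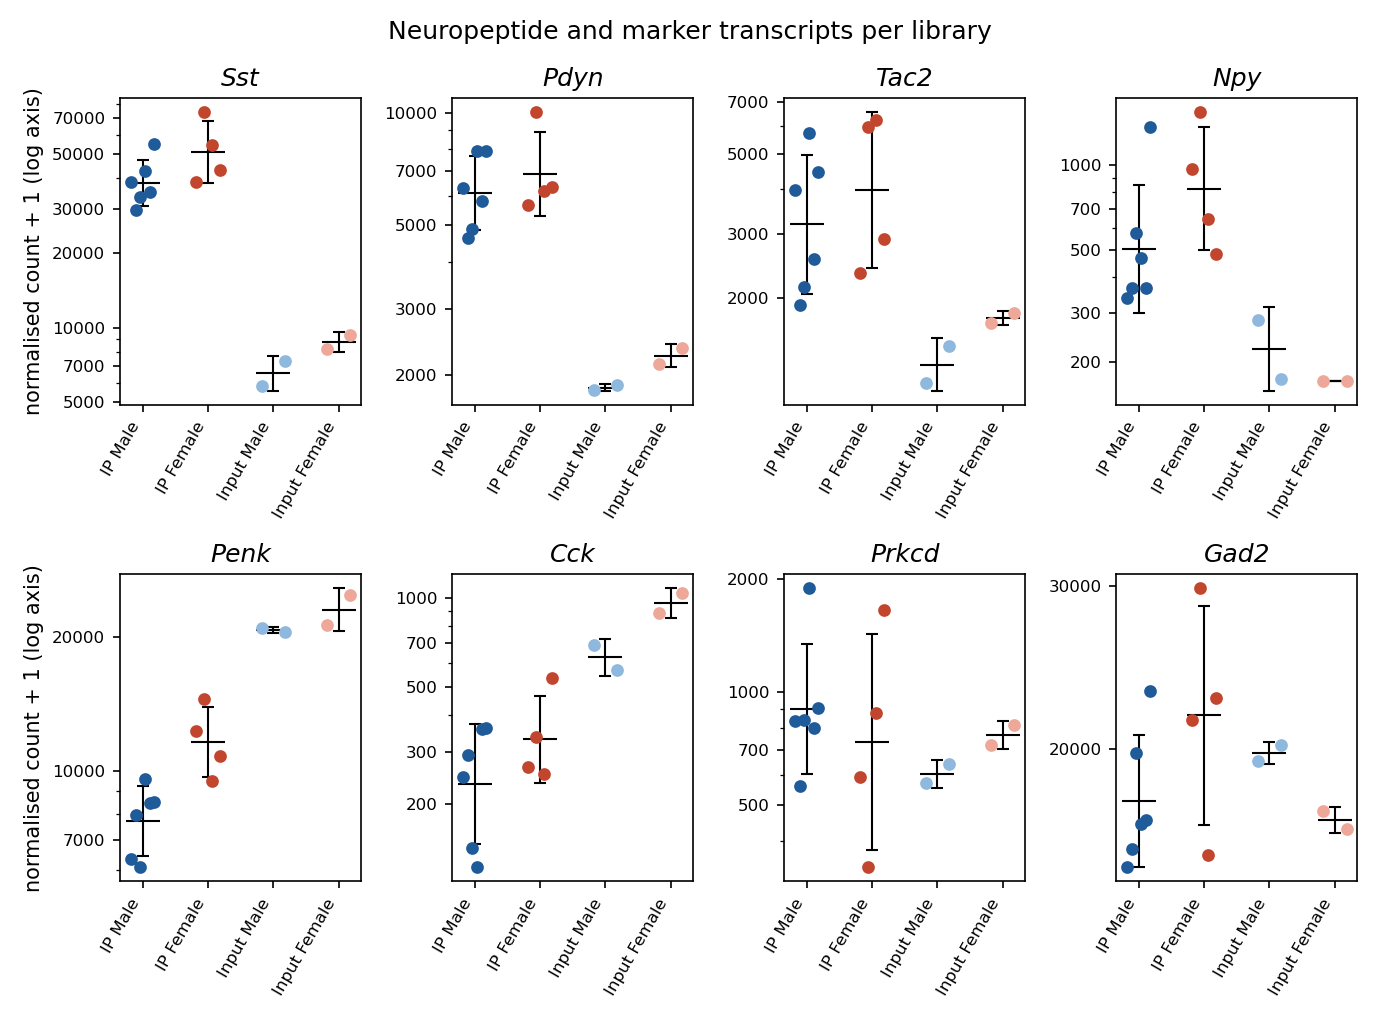
Normalised count plus 1 (log axis) of 8 peptide and marker genes in each of the 14 libraries by labelled group. Points are libraries, horizontal bars are means of log2 values and whiskers 1 SD on that scale. Sst and Pdyn lie above all input libraries in all 10 IP libraries, and Penk and Cck below them.

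Across all genes, 1052 of 13305 tested passed in IP against input, 687 higher and 365 lower (limma, adjusted p under 0.05). The largest increases among called genes with a mean normalised count of at least 100 were in the cytoskeletal linker Plec (log2 fold change 3.87), the actin crosslinker Flna (3.74), Ccdc108 (3.74), the noncoding RNA Snhg11 (3.56), the histone methyltransferase Kmt2a (3.56), the dynein heavy chain Dync1h1 (3.42), Col6a1 (3.42), Fn1 (3.42), Rnpc3 (3.41) and Celsr3 (3.39). Ccdc108 varied more than its mean, at 235.6 ± 291.7 (SD, n = 10) normalised counts in IP, and lay above the input libraries in 9 of 10 IP libraries. The smallest adjusted p-values among higher genes after Sst belonged to 4932438A13Rik, Ranbp2, Akap6 and Smg1, with log2 fold changes of 3.08, 2.75, 2.37 and 3.05. The largest decreases with the same minimum were in Ighmbp2 (-5.03), Cldn10 (-4.45), C1qb (-4.43), Cd63 (-4.00), Htra1 (-3.84), Trf (-3.80), Efhd1 (-3.79), Tspan12 (-3.72), Gpr37l1 (-3.72) and Cartpt (-3.71). With edgeR these decreases were smaller, from -3.89 for Ighmbp2 to -1.85 for Efhd1, with -2.92 for Cldn10, -3.03 for C1qb, -2.70 for Cd63 and -2.17 for Tspan12. Efhd1 stood at 515.9 normalised counts in IP_Male replicate 4, above all input libraries. The smallest adjusted p-values among lower genes belonged to Cst3, Clu, Sparcl1, Fth1 and Apoe, with log2 fold changes from -2.70 to -2.05.

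The number of calls rested on the few input libraries, and its split on the scaling, the filter and sample quality weights. Without Input_Male replicates 1 and 2 the number fell to 640 and 686, and without Input_Female replicates 1 and 2 to 592 and 545. Whichever input library was left out, the remaining calls were all among the 1052, and 124 to 161 of them were lower. The fit used 1 spread for IP and input, although input libraries varied far less, so fewer input libraries raised the error whichever was left out. In these fits the median log2 fold change of all genes lay from -0.3543 to -0.3415. With no filter 707 genes were higher and 1118 lower, and with sample quality weights 1569 were higher and 2223 lower. The median log2 fold change of all genes was -0.35, against 0.21 with edgeR and 0.12 with DESeq2 on recovered reads. It was -0.55 after upper-quartile rescaling, where 504 genes were higher and 558 lower, and -0.12 after quantile normalisation, where 745 were higher and 756 lower. The edgeR test called 973 genes, 775 higher and 198 lower, and DESeq2 called 1191 higher and 322 lower. The edgeR calls included 686 of the 687 higher genes but 196 of the 365 lower genes. Of the genes named here, C1qb, Cldn10, Cd63, Efhd1, Tspan12, Slc17a7, Map2 and Calb1 lost their call with edgeR. Of 73 named genes called, 54 kept their call without any 1 library. The other 19 lost it without at least 1 of the 4 input libraries: C1qb, Calb1, Cartpt, Ccdc108, Cck, Cd63, Cldn10, Csf1r, Efhd1, Grin2b, Grm7, Htra1, Map2, Per1, Slc17a7, Trf, Tspan12, Uqcrh and Vgf. Of these, Ccdc108, Efhd1, Per1, Slc17a7 and Tspan12 also lost it without single IP libraries.

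Many glial markers fell. Of 20 astrocyte markers, 13 were lower and none higher, among them Clu (log2 fold change -2.08), the glutamate transporters Slc1a2 (-1.14) and Slc1a3 (-1.96) and the glycolytic enzyme Aldoc (-2.07). Of 18 oligodendrocyte markers, 10 were lower, among them the myelin gene Mal (-2.30). Of 19 microglia and macrophage markers, 8 were lower, among them P2ry12 (-2.88) and Csf1r (-2.45). With edgeR, 11, 9 and 4 members of these lists were lower, and adjusted over the list alone with limma, 16, 15 and 17 were. Against other genes the lists had camera adjusted p-values of 4.10e-13, 5.03e-10 and 4.03e-09, and adjusted p = 0.0148, 0.0408 and 0.0207 with an estimated correlation. Not every glial gene followed: Gfap stood at 258.8 ± 261.9 (SD, n = 10) normalised counts in IP and 244.1 ± 58.1 (SD, n = 4) in input, and Mbp at 3783 ± 1990 (SD, n = 10) and 4637 ± 403.7 (SD, n = 4). Of 13 oligodendrocyte precursor markers, Olig1 alone was lower (-2.56), 4 were lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0626). It passed without IP_Male replicate 5 (adjusted p = 0.0482), IP_Female replicate 1 (0.0346) or Input_Female replicate 2 (0.0475). Of 20 endothelial and mural markers, Flt1 alone passed, with a log2 fold change of 2.48 (list camera adjusted p = 0.851). Of 6 ependymal and choroid plexus markers, 2 were lower with limma and 1 with edgeR (camera adjusted p = 0.327).

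Some markers of glutamatergic neurons were lower as well. Of 17 glutamatergic markers, 5 were lower, among them Rorb (log2 fold change -1.24), Cck and the vesicular transporter Slc17a7 (-2.04), with camera adjusted p = 0.00187 and adjusted p = 0.0737 with an estimated correlation. Adjusted over the list alone, 2 were higher and 10 lower, and with edgeR 1 was higher and 2 were lower. None of the 19 GABAergic identity genes passed with limma or with edgeR, 1 passed with DESeq2, and 1 higher and 2 lower had an unadjusted p under 0.05 (camera adjusted p = 0.780). Of 22 pan-neuronal genes, Map1b rose by 1.51 and Map2 fell by 0.55 (camera adjusted p = 0.410). Of 12 markers of other interneurons and cholinergic neurons, 3 were lower with limma and 0 with edgeR (camera adjusted p = 0.303). Of 20 striatal projection neuron markers, 2 were higher, among them the transcription factor Bcl11b (1.29), and 2 were lower, among them Penk (camera adjusted p = 0.851). Adjusted over the list alone, 4 striatal markers were higher and 2 lower.

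Some voltage-gated channel genes rose. Of 25 calcium, sodium and HCN channel genes, 9 were higher, none lower and 16 did not pass. The higher members included Cacna1e (log2 fold change 1.66, limma adjusted p = 1.44e-06), Cacna1a (1.95) and Cacna1b (1.55). Cacna1c stood at 1108 ± 227.3 (SD, n = 10) normalised counts in IP and 388.1 ± 69.9 (SD, n = 4) in input. The list had camera adjusted p = 2.39e-07, adjusted p = 0.0148 with an estimated correlation, and 10 higher members when adjusted over the list alone. With the trend of expression on the span of a gene in the genome removed and library means kept, a setting chosen after seeing the data, 1 member was higher and 1 lower, and the list stayed on the higher side (camera adjusted p = 0.00707). Of 37 potassium channel genes, 2 were higher, among them the sodium-activated channel Kcnt1 (1.92), and Kcnj10, the inward rectifier of astrocytes, was lower (-1.28), with camera adjusted p = 0.0945. Of 24 glutamate receptor genes, Grin2b (0.88) and Grm7 (1.42) were higher and 2 were lower, of which none was lower with edgeR or DESeq2, and 3 and 2 passed when adjusted over the list alone (camera adjusted p = 0.0945). None of the 16 GABA receptor genes passed with limma, edgeR or DESeq2, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.516). With the span trend removed and library means kept, 4 were lower and the list passed on the lower side (camera adjusted p = 0.00184). None of the 27 monoamine and acetylcholine receptor genes passed with these tools, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.327). Of 29 neuropeptide receptor genes, Ntsr2 alone passed, at -2.89, and 3 were lower when adjusted over the list alone (camera adjusted p = 0.0711). Ntsr2 is also a member of the astrocyte list and was counted as lower there. The 8 opioid genes held 1 higher member, Pdyn, and 1 lower, Penk (camera adjusted p = 0.591). Of 20 peptide processing and secretion genes, 4 were higher, among them Pam (1.13) and Vgf (1.13), and 3 were lower, among them the carboxypeptidase Cpe (-1.53) and Scg3 (-1.26), and 6 and 4 passed when adjusted over the list alone (camera adjusted p = 0.780). Of 20 immediate early genes, Per1 alone passed, at 1.12 (camera adjusted p = 0.591).

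Among RNA classes, some nuclear noncoding RNAs were higher and many transcripts of ribosomal proteins lower, and neither list passed with an estimated correlation. Of 12 nuclear long noncoding RNAs, 5 were higher, among them Snhg11, Rian and Kcnq1ot1 (log2 fold change 1.91), with camera adjusted p = 3.14e-05 and adjusted p = 0.0809 with an estimated correlation. Of 57 ribosomal protein genes, 27 were lower and none higher, among them Rpl10 (-2.25), Rpl3 (-1.39), Rps24 (-1.73) and Rpl32 (-1.88). Their list had camera adjusted p = 2.13e-20, and adjusted p = 0.0827 with an estimated correlation, and 47 were lower when adjusted over the list alone. Of 39 nuclear-encoded oxidative phosphorylation genes, 6 were lower, among them Atp5g3 (-1.46) and Uqcrh (-1.42), and 9 were lower when adjusted over the list alone, with camera adjusted p = 2.87e-05 and adjusted p = 0.157 with an estimated correlation. Of 9 sex-linked genes, the X-linked demethylase Kdm6a alone was higher (1.74), 2 were higher when adjusted over the list alone, and the list had camera adjusted p = 0.0263 and adjusted p = 0.0809 with an estimated correlation. It missed the threshold without Input_Male replicate 1 (adjusted p = 0.0527) and replicate 2 (0.0597) and with DESeq2 (0.191). The sex-linked list holds Xist and Y-linked genes, and by label IP had 6 male and 4 female libraries against 2 and 2 in input. The fit had no sex covariate, so the ratio of the sexes and enrichment cannot be told apart for Xist and the Y-linked genes. Kdm6a stood at 1527 ± 1038 (SD, n = 6) normalised counts in IP_Male and 1219 ± 640.3 (SD, n = 4) in IP_Female. In input it stood at 488.5 ± 78.6 (SD, n = 2) in Input_Male and 267.1 ± 6.69 (SD, n = 2) in Input_Female. All 10 IP libraries lay above all 4 input libraries, which argues against the ratio as the whole cause for Kdm6a. In all, 9 of 26 lists passed, 3 on the higher and 6 on the lower side relative to other genes, 4 of them with an estimated correlation. For the lists with no count adjusted over the list alone given here, that count equalled the count over all genes. In 6 lists the median fold change lay below 0 while the test pointed to the higher side: pan-neuronal genes, endothelial and mural markers, central amygdala neuropeptides, peptide processing genes, striatal markers and immediate early genes. The mean was below 0 and the median above it for glutamate receptors and potassium channels, and the reverse for pan-neuronal genes.

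**Figure D2:**
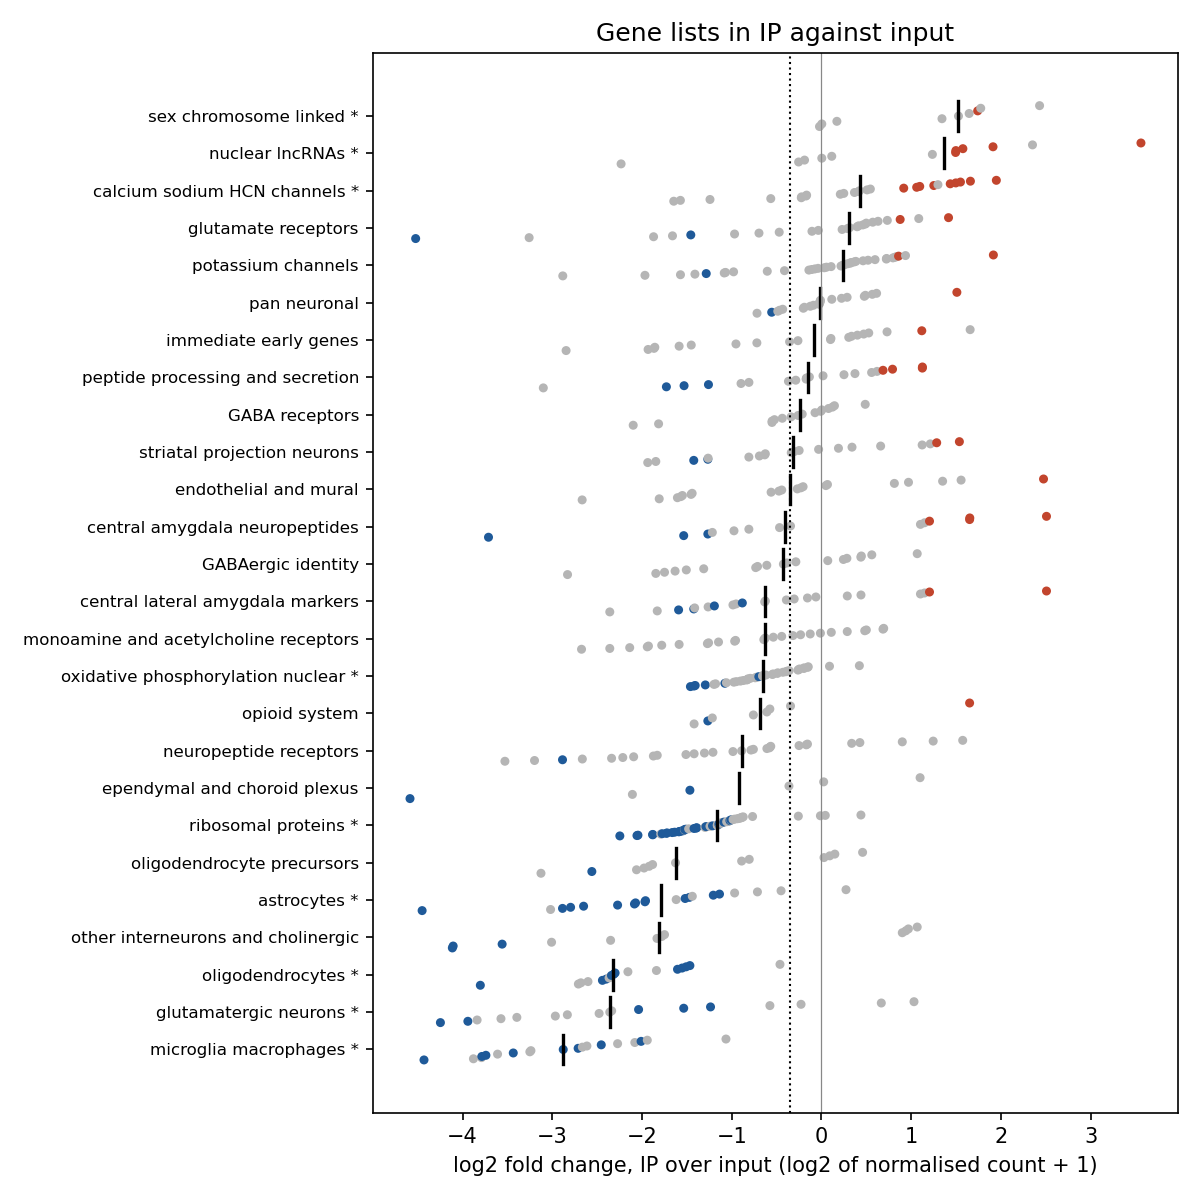
Log2 fold change of IP over input (x axis) for each measured member of the 26 gene lists. Coloured points passed the threshold (red higher, blue lower), grey points did not, black bars are list medians, the dotted line is the median of all genes (-0.35), and asterisks mark the 9 lists that passed with camera. The medians of the 3 glial lists of astrocytes, oligodendrocytes and microglia lie to the left of that line.

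Higher genes had long spans in the genome and lower genes short ones, and transcript length was not tested. The median span of a gene in the genome was 86.1 kb among genes called higher, 17.8 kb among genes called lower and 25.9 kb among all tested genes. In the tenth of genes with the longest span, 14.2% were called higher and 1.58% lower, and in the tenth with the shortest span 0.453% were higher and 4.60% lower. Across genes, which are not independent replicates, the fold change and the span had a Spearman rho of 0.298, and 0.177 with edgeR. With the trend on span removed in each library, a setting chosen after seeing the data, 309 genes were higher and 612 lower where library means were kept, and 454 were higher and 316 lower where library medians were kept. Of the 687 higher genes, 296 and 402 kept their call under these settings. Where means were kept, Cacna1a, Cacna1b, Cacna1c, Bcl11b, Grin2b, Grm7, Pam, Flt1, Kdm6a and Kcnq1ot1 lost it as their log2 fold changes fell by 0.62 to 0.79, and the median of all genes went to -0.56. Grin2b went from 0.88 (SE 0.23) to 0.12 (SE 0.29) and Cacna1a from 1.95 (SE 0.35) to 1.22 (SE 0.37), with a limma adjusted p of 0.0512 for the latter. Ccdc108 lost its call with a fold change that moved by less than its error, from 3.74 (SE 1.11) to 3.43 (SE 1.14). Sst, with a span of 1.77 kb, and Pdyn, with 13.4 kb, kept it.

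**Figure D3:**
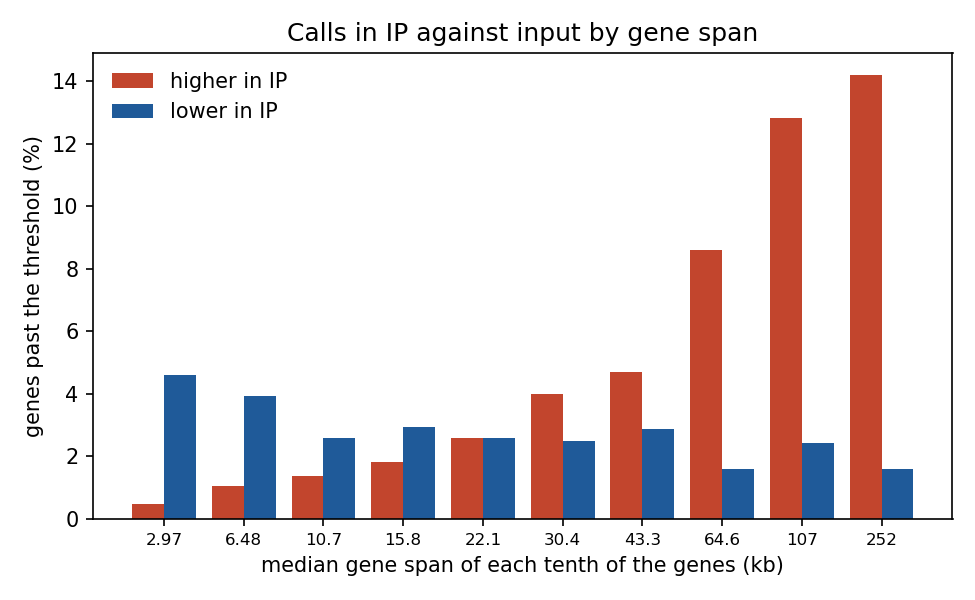
Share of genes past the threshold in IP against input (y axis, %) in 10 equal groups of genes ordered by span, with the median span of each group on the x axis (kb). Red bars are genes higher in IP and blue bars genes lower; the share called higher goes from 0.453% to 14.2%.

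The authors' deposited table of the same comparison called 1553 genes at an adjusted p of 0.05, 1158 higher and 395 lower in IP. Of the 1052 genes called here, 955 were also called in the authors' deposited table, all with the same sign, 686 higher and 269 lower. Among the tested genes the authors' table made 1525 of its calls, and lists independent of each other would share 59.8 higher and 10.1 lower genes there. Both rest on the same libraries, so the overlap compares methods. Across 13305 genes, the fold changes here and in the authors' deposited table had a Pearson r of 0.875 and a Spearman rho of 0.866. For Sst the authors' deposited table gives a log2 fold change of 2.47.

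The labels also give the sex of each pool, so the libraries can be compared between sexes. Transcripts of the X-inactivation gene Xist and of 4 Y-linked genes matched the label in all 10 IP libraries and went against it in all 4 input libraries. Xist stood at 11920 ± 4912 (SD, n = 4) normalised counts in IP_Female and 23.9 ± 33.7 (SD, n = 6) in IP_Male. In input it stood at 3841 ± 858.6 (SD, n = 2) in the libraries labelled Input_Male and 5.80 ± 2.90 (SD, n = 2) in those labelled Input_Female. Ddx3y stood at 502.9 ± 224.7 (SD, n = 6) in IP_Male and 428.7 ± 8.56 (SD, n = 2) in the libraries labelled Input_Female. It had no reads in either library labelled Input_Male, where 3 reads would be 4.48 and 3.75 normalised counts. Xist lies on chromosome X from 103460373 to 103483233 and Ddx3y on chromosome Y from 1260715 to 1286628 (GRCm38.p6).

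**Figure D4:**
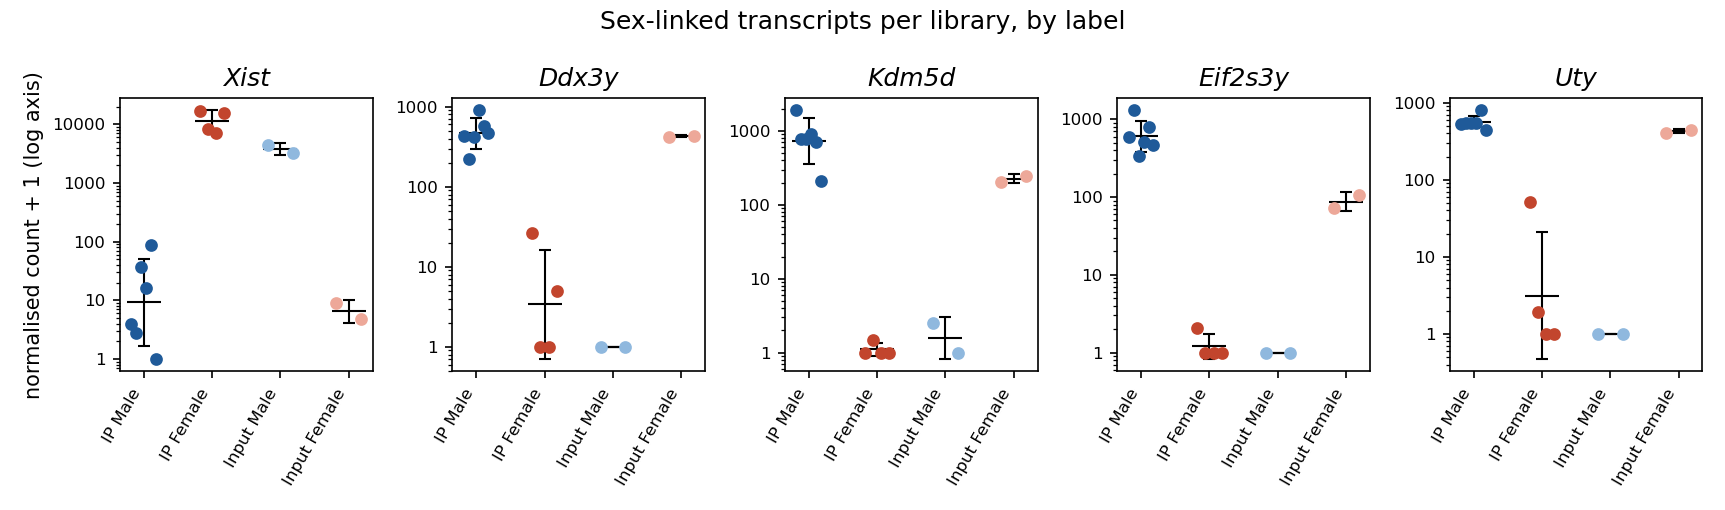
Normalised count plus 1 (log axis) of Xist and 4 Y-linked genes in each of the 14 libraries, by labelled group. Points are libraries, horizontal bars are means of log2 values and whiskers 1 SD on that scale. The libraries labelled Input_Male hold Xist and the libraries labelled Input_Female hold Y-linked reads.

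Between female and male IP libraries, the genes called with limma were mostly on the sex chromosomes. Xist was higher in IP_Female, and Kdm5d, Eif2s3y, Ddx3y, Uty and the transcription factor Runx1 were lower, so that 6 of 13305 genes passed with limma. Runx1 stood at 130.6 ± 138.9 (SD, n = 6) in IP_Male and 0.582 ± 0.878 (SD, n = 4) in IP_Female (limma adjusted p = 0.0448). Sst and Pdyn had log2 differences of 0.41 (SE 0.18, limma adjusted p = 0.606) and 0.17 (SE 0.22, limma adjusted p = 0.876). DESeq2 on recovered reads called 131 genes and edgeR 4, and 1059 genes had an unadjusted p under 0.05 with limma. In simulated data this comparison made 2 false higher and 7 false lower calls. Runx1 lost its call with edgeR, with the 10 IP libraries alone and without most single libraries, and the count was 9 without IP_Female replicate 1.

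Between the input libraries the difference ran against the labels. Xist was lower in the libraries labelled Input_Female than in those labelled Input_Male, and it was the 1 gene past the threshold in the model of all 14 libraries (limma adjusted p = 0.00770). Ddx3y and Uty had reads only in the libraries labelled Input_Female, each with a limma adjusted p of 0.0637. Xist lost its call when any 1 of the 4 input libraries was left out, and 3 genes passed when any 1 of the 4 IP_Female libraries was. With the spread taken from the 4 input libraries alone, 630 genes passed. The 2 input groups also differed in other RNA. A score over 11 nuclear noncoding RNAs was 0.785 and 0.702 in the libraries labelled Input_Male and -0.112 and -0.0814 in those labelled Input_Female. Rpl3 had mean normalised counts of 2395 and 3169 in these groups (n = 2 each). Sex and other differences between the groups cannot be told apart here, so the 630 genes cannot be assigned to sex.

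Within each labelled sex, Sst and Pdyn were again higher in IP. The log2 fold change of Sst was 2.56 (SE 0.23, limma adjusted p = 4.24e-07) against the libraries labelled Input_Male and 2.54 (SE 0.25, limma adjusted p = 1.63e-06) against those labelled Input_Female. That of Pdyn was 1.73 (SE 0.28) and 1.61 (SE 0.30). By label, in males 243 genes passed, 201 higher and 42 lower, and in females 273 passed, 222 higher and 51 lower. These calls include Xist and the 4 Y-linked genes, as the sex-linked transcripts of the input libraries went against their labels. The splits moved with the scaling, to 220 higher and 116 lower in males and 216 and 129 in females after quantile normalisation, and to 149 and 64 in males and 162 and 88 in females after upper-quartile rescaling. Of the 243 and 273 genes, 155 higher and 28 lower were called in both, where independent lists would share 3.35 and 0.161. The counts fell when 1 input library of the same label was left out, which left 1 in that group. The fit used 1 spread for IP and input, so a smaller input group raised the error. The median log2 fold change of all genes in males went from -0.287 to -0.277 and -0.292 without Input_Male replicates 1 and 2. In females it went from -0.342 to -0.339 and -0.352 without Input_Female replicates 1 and 2. In females, 160 genes passed without IP_Female replicate 4 and 424 without IP_Female replicate 2, and 63 without both IP_Female replicates 1 and 4, which was chosen after seeing the data.

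The enrichment differed by labelled sex for sex-linked genes. Xist, Kdm5d, Uty, Ddx3y and Eif2s3y were the 5 genes past the threshold in the interaction of sex and pulldown with limma, and 32 had an unadjusted p under 0.05. Fitted fold changes of these genes against groups without reads are not bounds. Sst and Pdyn had interactions of -0.01 (SE 0.34) and -0.11 (SE 0.41) on the log2 scale, each with a limma adjusted p of 0.9998. With the sex labels of the input libraries exchanged, a setting chosen after seeing the data, 0 genes passed with limma and 79 had an unadjusted p under 0.05. With those labels exchanged, 438 genes passed in males and 88 in females.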

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

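Chosen only after the results were seen were the 3 tests of the sex labels, the removal of the span trend, the counts of lower calls and of glial lists with edgeR, the other splits for lists with an estimated correlation, and the interaction with exchanged labels.

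Xist and the Y-linked genes went against the sex labels of the input libraries. The interaction of sex and pulldown passed for Xist (19.43 on the log2 scale), Ddx3y (-15.84), Eif2s3y (-15.42), Kdm5d (-16.54) and Uty (-16.2). Mixed sexes would leave signal of both in a library, but the highest share of the other sex's signal in an input library was 0.204%, and a sex difference in transcription would keep Y-linked reads in male pools, but those of the libraries labelled Input_Male were 0.0285% of the IP_Male level. All 5 genes lay on the side of the other sex in 4 of the 4 input libraries, so that the sex labels of the 2 input groups may be exchanged. With the labels exchanged, 0 genes passed in the interaction with limma (79 at an unadjusted p under 0.05), and where the exchange arose stays open.

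Genes with a long span were more often called higher in IP, and 5 of 12 nuclear noncoding RNAs were (list adjusted p = 0.0809 with an estimated correlation). The span trend as the whole cause is argued against by 296 of 687 higher genes that stayed called with the trend removed and library means kept (402 with medians kept). Nuclear RNA carried into the IP libraries may contribute. Across the 10 IP libraries the nuclear noncoding RNA score and the excess of long over short genes had a Pearson r of 0.679. Its permutation p was 0.0359, adjusted 0.0539 over 3 relations. The Spearman rho was 0.612 (permutation p = 0.0676, adjusted 0.101), and r was 0.571 without the 2 farthest libraries. Other values went the other way. The nuclear noncoding RNA Malat1 took 0.663% to 4.25% of reads in IP libraries and 2.72% to 3.60% in input. IP_Male replicate 4 and IP_Female replicate 2 had lower nuclear scores (0.464 and 0.498) than both Input_Male libraries (0.785 and 0.702). Their long-over-short scores (1.12 and 0.904) still lay above all input libraries, at most 0.826. More neuronal RNA with longer genes as the whole cause stays open: among 70 glial genes, which are not independent replicates, fold change and span had a Spearman rho of 0.229 (permutation p = 0.0577) and a Pearson r of 0.312 (permutation p = 0.0084, r 0.222 without the 2 farthest genes), and the latter goes against it. A biological difference between SOM+ neurons and the tissue also stays open and untested, and these libraries cannot tell it apart from the pulldown itself.

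Genes lower in IP came with a wide spread of the IP libraries. Sequencing depth is argued against, since at a common depth of 4433890 reads the IP libraries held at most 13732 genes and the input libraries at least 15507. Libraries with few reads of a gene as the whole cause of lower calls is argued against by the 196 of 365 genes that edgeR also called lower, while for the others this stays open. Fewer glial transcripts in IP stays open: 3 of 3 glial lists were lower by camera with edgeR, but limma had already called them on these libraries, so the edgeR count adds no support.

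Other splits of the libraries were drawn, 100 per result, the real one included. For genes in IP against input, 1 split gave as many as the real 1052, the real one, so no other split drawn reached it. The draws were 100 of 1001 possible splits. Every other split sets IP libraries, with their wide spread, in both groups, so the share measures chance only loosely. The highest other gave 434, with IP_Male replicates 3 and 5 and IP_Female replicates 1 and 4 set against the rest. This points to a structure within the IP libraries. For gene lists, 7 splits gave as many as the real 9 and the highest other gave 10, so chance is not excluded for that number. With an estimated correlation, 1 split gave as many as the real 4, the real one, and the highest other gave 1. The limits given for the number of genes hold for these lists too. For sex in IP, 3 of the 100 splits gave as many as the real 6, the real one included, a low share. Yet the highest other gave 106, with IP_Male replicates 1 and 4 and IP_Female replicates 2 and 3 together. This points to a structure of the samples, so chance is not excluded for that number. Besides Xist and the Y-linked genes, which follow sex, the 6 held only Runx1.

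An outlying library was found in 16 of 182 groups of values tested, where chance gives about 5%. In 2 of the 16, Eif2s3y and Kdm5d, the value is 1 read set against 0 reads and says nothing about the library. Lone values in IP_Male replicate 4 were Cacna1c at 786.5 (others from 1071 to 1276), Rpl10 at 1810 (338.5 to 621) and Rpl3 at 1748 (748.2 to 938.6) normalised counts. In IP_Male replicate 5 they were Uty at 791.8 (443.9 to 551.2), Gpr37l1 at 1.641 (66.54 to 233.5) and Rpl32 at 130.5 (247.1 to 359.3). In IP_Male replicate 6 they were Gad1 at 3961 (2074 to 2371) and Csf1r at 27.92 (164.9 to 450.7). In IP_Female replicate 1 they were Eif2s3y at 1.122 (1 read, 0 in the others), Uty at 50.49 (0 to 0.9432) and Grin2b at 1915 (2656 to 2680). In IP_Female replicate 2 they were Kdm5d at 0.4716 (1 read, 0 in the others), Dync1h1 at 5159 (12910 to 14160), Rnpc3 at 273.5 (1327 to 1765) and a total of 18520000 reads (9540000 to 10670000). In IP_Female replicate 4 it was Atp5g3 at 329.2 (977.6 to 1141).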

How the results depend on the processing

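Chosen after the results were seen were the fit without IP_Female replicates 1 and 4, both removals of the span trend and the exchanged input sex labels. The 1052 genes of IP against input became 1825 with no filter, which tests more genes, and 3792 with sample quality weights, which made false lower calls in simulated data. Sex in IP (6 genes) gave 131 with DESeq2 and 3 with a replicate block of number. Sex in input (1 gene) gave 0 with a pseudocount of 0.5 (7 at an unadjusted p under 0.05), 3 with a pseudocount of 8 or upper-quartile rescaling, 4 with quantile normalisation or DESeq2, 2 with edgeR, 22 with no filter, 771 with weights and 630 with the 4 input libraries alone. Males (243 genes) gave 712 with no filter, 2688 with weights, 583 with DESeq2 and 438 with exchanged input sex labels. Females (273 genes) gave 566, 1239, 677 and 88 under these settings, and 63 without IP_Female replicates 1 and 4. With no filter more genes were lower than higher, with 227 higher and 485 lower in males and 222 and 344 in females. In males the same held with weights (1241 higher and 1447 lower), but not in females (683 and 556). The interaction (5 genes) gave 0 with exchanged labels. With them the log2 difference of Xist in input turned to 9.193 by construction, and the interactions of Ddx3y and Uty, neither called there, to 1.654 and 1.265. Of the 9 lists, 4 passed with an estimated correlation. The rotation test fry, which does not compare with other genes, gave 15 of all 26 lists, some of them outside the 9. For Sst, 4 pairs gave 2.496 on the log2 scale and an exact p of 0.125, the smallest 4 pairs allow. The authors' 1553 genes became 1008 at a threshold of 0.01. For the other moved results the cause was not tested. Leaving out 1 library gave 545 to 1171 genes for IP against input, 5 to 9 for sex in IP, 0 to 3 for sex in input, 5 to 5 for the interaction, 24 to 339 in males, 10 to 424 in females, 8 to 11 lists, and 2.383 to 2.609 for Sst. Where this left 1 library in a group, it was assumed to vary like the others. Replicate numbers gave no sign of pairing (r between libraries of 1 number from -0.0601 to 0.0346, and from -0.0356 to 0.0309 between IP and input with exchanged input labels). Input libraries of a group differed little from each other, so a low r with them cannot exclude pairing. A block of number or of sex and number, with the labels as given, gave 1163 genes, 1228 in the 8 paired libraries, 256 in males, 247 in females, 5 in the interaction and 1 for sex in input. Among 805 values of 26 lists under alternatives, 767 kept side and direction, 14 lost their call, 24 gained one and 0 reversed. Among 2610 values of 87 named genes in IP against input the numbers were 2446, 146, 18 and 0. Among 324 values of 12 genes of the sex contrasts they were 286, 35, 0 and 3. Depth limits the zero counts of Y-linked genes, where 3 reads are 4.48 and 3.75 normalised counts in the libraries labelled Input_Male.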

Other observations

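The gene families here were defined by symbol prefixes after the comparison of all genes was known, though before they were tested as families. Their members named here were chosen after their values were seen. Kmt2a, Dync1h1, Col6a1 and Snhg11, among the largest increases, belong to such families. The family p-values are therefore descriptive and give no independent support.

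Of 24 families compared in IP against input, 11 were higher and 3 lower relative to other genes by camera, and 4 passed with an estimated correlation. With the span trend removed 8 passed, among them the Zfp zinc finger genes (camera adjusted p = 0.0112), which had not passed before (0.225). Span is a distance in the genome, and transcript length and GC content were not tested. Ankyrins and spectrins were higher in 8 of 8 members, among them Sptbn1 (log2 fold change 3.03) and Ank3 (2.99), with adjusted p = 9.53e-15, and 0.0463 with an estimated correlation. HECT and UBR ubiquitin ligases were higher in 11 of 15 members, among them Herc2 (2.44) and Huwe1 (1.37), with adjusted p = 2.06e-16, and 0.0355 with an estimated correlation. Histone methyltransferases and CHD remodellers were higher in 13 of 24 members, among them Kmt2c (2.08), Setd2 (2.18) and Chd6 (2.23), with adjusted p = 2.36e-16, and 0.0506 with an estimated correlation. RNA helicases and splicing factors were higher in 12 of 80 members, among them Prpf8 (2.32) and Srrm2 (1.10), with adjusted p = 5.86e-05, and 0.0355 with an estimated correlation. Dyneins were higher in 5 of 22 members, with adjusted p = 8.14e-05, and 0.0463 with an estimated correlation. Mitochondrial ribosomal proteins were lower as a family of 76 with 0 members called by limma (adjusted p = 0.00847, and 0.305 with an estimated correlation).

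Across the 10 IP libraries the nuclear noncoding RNA score went against Sst, with a Pearson r of -0.784 (permutation p = 0.00699, adjusted 0.0210 over 3 relations) and a Spearman rho of -0.818 (permutation p = 0.00572, adjusted 0.0172), and r was -0.672 without the 2 farthest libraries. With the number of genes detected it had r = 0.121 (permutation p = 0.734) and rho = 0.152 (permutation p = 0.684), and r was 0.193 without the 2 farthest.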
